A study of Homo sapiens with 4 samples.

How the data were processed

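Chromatin immunoprecipitation sequencing (ChIP-seq) was done on human cells that the labels call HSC, with the cell type given as stem cells and progenitors. The 4 libraries were a ChIP and an input library from control cells and a ChIP and an input library from cells treated with transforming growth factor β1 (TGF-β1, 20 ng/mL, 2 h, per the labels). Input is sheared chromatin that was not immunoprecipitated, and it measures the local background. The antibody is not given in the sources used here. The treatment protocol, the same in the labels of all 4 libraries, controls included, also names GDF11 at 100 ng/mL as the other treatment. The library names give only control and TGF-β1, and whether any of these cells received GDF11 is not given in the sources used here. Chromatin was prepared with a Diagenode kit for large numbers of cells, per the labels. Each group held 1 library, so there were no replicates and no test between conditions was made.

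The authors aligned the reads with Bowtie2 to hg38, per the submitters' processing notes. The notes name MACS2 2.1.0 as peak caller, whereas the file headers name version 2.2.7.1. Peaks were called in each condition separately, with 1 ChIP library against its own input, at a q-value limit of 0.05 and an effective genome size of 2700000000 bp, keeping 1 tag per position, per the file headers. Whether reads were filtered on mapping quality, or peaks on a list of problem regions, is not given in the sources used here. The deposited pileup is a signal, the coverage of ChIP tags extended to the fragment length at the peak's summit, and the larger library was scaled to the smaller one per the file headers. The deposited fold enrichment is the ratio of pileup plus 1 to local background plus 1, where the local background is the highest of the genome-wide value and the input values around the summit. The deposited −log10 p-value and −log10 q-value of each peak come from a Poisson test of the pileup against that background, per the authors' peak caller. All 3 are the peak's own values and were used to describe, rank or filter peaks within a list. Positions and lengths are those the authors deposited, counted from 1 on hg38.

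The depth of each library was taken from the file headers. The control ChIP library held 45477270 tags, 36280696 after removal of duplicates, and its input 83620763, 66537905 after removal. The TGF-β1 ChIP library held 57857040 tags, 45984282 after removal, and its input 56019809, 46802425 after removal. Redundant tags made up 20% and 21% of the ChIP libraries and 20% and 16% of the inputs, control first. Tag length was 60 bp in the control and 43 bp in the TGF-β1 library, and the fragment length used by the caller was 148 bp and 136 bp.

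The local background at each summit was computed from pileup and fold enrichment. Its lowest value equalled the genome-wide background in the headers, 1.99 tags in the control and 2.32 in the TGF-β1 library, and the p-values recomputed from it differed from the deposited ones by at most 0.00021 on the −log10 scale. A peak was said to lie over high local background when that value exceeded 5 times the genome-wide one. Bins of 1 Mb with at least 20 peaks of both lists together were called dense (65 bins, against a median of 5 peaks per bin that held any). Overlap was counted from 1 bp. Chance overlap was measured by 1000 random placements of each peak on its own chromosome and by 1000 shifts of each peak by 10 to 50 kb, and chromosome lengths were taken as the last coordinate of any gene or peak, with assembly gaps not left out. Shares have Wilson 95% intervals, numbers of peaks in a region have exact Poisson intervals, and ratios of 2 counts have exact intervals. All of these cover counting error only. Where a count was 0, the share that 3 counts would give is stated as the limit.

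Genes were taken from a RefSeq table of the same build with 59084 genes, 19974 of them protein-coding. The table gives each gene's first and last base, but neither strand nor exons were used here, so distances are to the gene body or to its nearer end, and the planned share of peaks at transcription start sites was replaced by the share within 1 kb of either end of a protein-coding gene. Positions in exons, introns and untranslated regions were not analysed. Without a genome sequence, the 23 planned motifs were not run. A gene was said to have a peak when a summit was nearer to it than to any other protein-coding gene and within 100 kb. For each of 18 gene lists (813 genes), the number of members with a peak was set among 10000 random lists of the same size, matched on deciles of the stretch of genome nearest to each gene, with ties shared equally between above and below. The β-globin region ran from the lower end of HBB to 30 kb past HBE1, the α-globin region from 60 kb before HBZ to the end of HBQ1, and the MYC region covered 2 Mb on each side of MYC. Each was set beside 10000 windows of the same length drawn at random outside the dense bins.

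The gene lists, regions and most alternatives were fixed before the data were examined. The local background with its limit of 5 times the genome-wide value, the dense bins, the shifts of peaks and every value split by these were added after the data had been seen. The named genes were also fixed by rule. The rule takes every peak in the 3 regions (the 6 of highest fold where a list had more), and on chromosomes 1 to 22 and X the 10 TGF-β1 peaks without overlap, the 10 with overlap and the 5 control peaks without overlap of highest fold, by their nearest protein-coding gene. It adds up to 4 members of each list by fold in the TGF-β1 list and up to 2 in the control list, and a set of single genes whatever their values, among them SMAD7, SKIL, ID1, MYC, GATA1, KLF1, TAL1 and BCL11A. Some genes that the rule takes are not reported here. HBD, PVT1, CCDC26, RN7SK, RN7SL1, RN7SL2, the other abundant RNA genes and the TGIF1 peaks other than the one of highest fold were looked up after the values had been seen.

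The code was tested on simulated data before use. All planted overlapping peaks were found (100.0%), gene distances equalled a direct search in 100.0% of random places, 6.5% of simulated lists with no effect fell outside the 2.5 to 97.5 percentiles, and a planted list reached the top percentile. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. The alternatives were stricter limits on q and fold, removal of the 1% of peaks with the highest pileup, overlap of at least 50% of both peaks or across gaps of up to 500 bp, lists of equal length, other distances to genes, and, added after the data were seen, removal of dense bins, restriction to low local background, other limits for high background and scaling to the control tag number. The β-globin peaks were also tested, after the data were seen, by binomial thinning of their pileup to the control tag number in 10000 draws, with the local background scaled alike and kept at or above the control's genome-wide value, and a peak was called at the lowest −log10 p-value of the control list. All TGF-β1 peaks were thinned in the same way in 1000 draws and counted by local background, and the ratio to the control number has an interval for counting error. The bound on that ratio was lowered from 1.5 to 1.1, and the bound on high-background peaks was moved to their ratio at a −log10 q of at least 10, after these values had been seen, because the ratio over high background was below 1.5 before thinning.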

Results

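The series compared chromatin of control cells and of cells treated with TGF-β1 for 2 h at 20 ng/mL, with attention to the β-globin and MYC loci in its title. Each condition had 1 ChIP library, called against its own input, and 1 peak list. The ChIP libraries held 36280696 (control) and 45984282 (TGF-β1) tags after removal of duplicates, a ratio of 1.27. Because there was 1 library per group, every difference below is between 2 libraries, and the intervals cover counting error only. Fold enrichment and −log10 q are the authors' values for each peak.

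At the β-globin locus, 5 peaks were called in the TGF-β1 list and 0 in the control list. They lay in HBB, the adult β-globin gene, in HBG1 and HBG2, the fetal γ-globin genes, and beside HBE1, the embryonic ε-globin gene. HBB (chromosome 11, 5225464 to 5227071, hg38) held 2 of them. One ran from 5225519 to 5225751 with a pileup of 32, a fold of 5.58 and a −log10 q of 11.6. The other ran from 5226622 to 5226804 with a pileup of 25, a fold of 6.59 and a −log10 q of 11.1, and ranked 46 by fold among the 15993 TGF-β1 peaks. The HBG1 peak (5248284 to 5248497) had a fold of 5.37 and a −log10 q of 6.47, and the HBG2 peak (5253226 to 5253365) a fold of 5.32 and a −log10 q of 7.03. HBG1 and HBG2 are nearly identical in sequence, so reads can be placed in either and these peaks are uncertain as to gene. The fifth peak (5271170 to 5271382) lay 1.38 kb past HBE1 with a fold of 2.61 and a −log10 q of 1.70. It lay at the near end of the 30 kb past HBE1, the stretch that holds the locus control region, the strong distal enhancer of these genes. In the rest of that stretch neither list had a summit. HBD, the δ-globin gene between HBB and HBG1, held no summit. The map of the locus shows these positions.

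**Figure D1:**
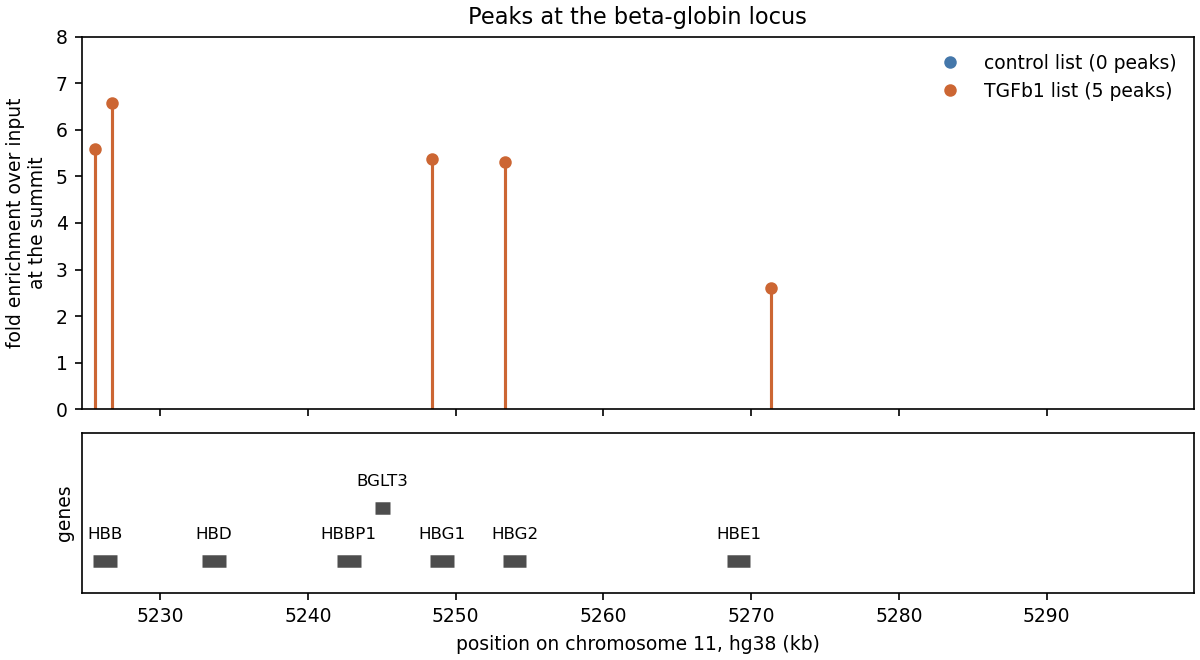
Peaks at the β-globin locus on chromosome 11 (hg38, position in kb on the x axis), with the authors' fold enrichment over input at each summit on the y axis and gene bodies as bars beneath. All 5 peaks belong to the TGF-β1 list, 2 of them in HBB and 1 each in HBG1 and HBG2, and the control list has none.

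Among 10000 random windows of the same length, 3 held as many TGF-β1 peaks, with a mean of 0.283 peaks per window. The 5 peaks have a Poisson interval of 1.62 to 11.7 and make up 0.0313% of the list (0.0134% to 0.0732%). The control count of 0 of 5307 allows a share of up to 0.0565%, and 92.2% of random windows also held no control peak. With lists of equal length by fold, 4 of 5307 TGF-β1 peaks lay at the locus, or 0.0754% (0.0293% to 0.194%), which is above that limit, but its interval overlaps that of 0 of 5307 (0% to 0.0723%).

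The α-globin locus (chromosome 16, 92644 to 181179), which holds HBA1 and HBA2 and their upstream enhancers, had 0 peaks in both lists. The nearest TGF-β1 summit was 76.1 kb from HBA1 and the nearest control summit 686 kb. A count of 0 allows a share of up to 0.0188% of the TGF-β1 list and 0.0565% of the control list, and 72.2% of random windows held no TGF-β1 peak.

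Within 2 Mb of MYC, the proto-oncogene that drives growth and proliferation, the control list had 3 peaks and the TGF-β1 list 13, and no peak of one list overlapped the other. None lay in MYC itself (chromosome 8, 127735434 to 127742951), in PVT1, the non-coding gene beside it, or in CCDC26, the non-coding gene whose body carries distal MYC enhancers used in blood cells. The nearest TGF-β1 summit lay 104 kb from MYC (peak 127631318 to 127631461, fold 4.52), and the nearest control summit 786 kb away (peak 126949150 to 126949308, fold 3.49). The TGF-β1 peak of highest fold (126683101 to 126683274, fold 6.33, −log10 q 8.74) was 1052 kb from MYC, inside the uncharacterised gene LOC105375751. That gene held 5 TGF-β1 summits and 2 control summits. The other TGF-β1 peaks of the highest folds were at 128159414 to 128159687 (fold 4.71), 127000131 to 127000288 (fold 4.38), 125842785 to 125842920 (fold 4.22) and 126263113 to 126263302 (fold 3.62). The other control peaks were at 126233471 to 126233645 (fold 5.52) and 126607044 to 126607223 (fold 4.57).

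**Figure D2:**
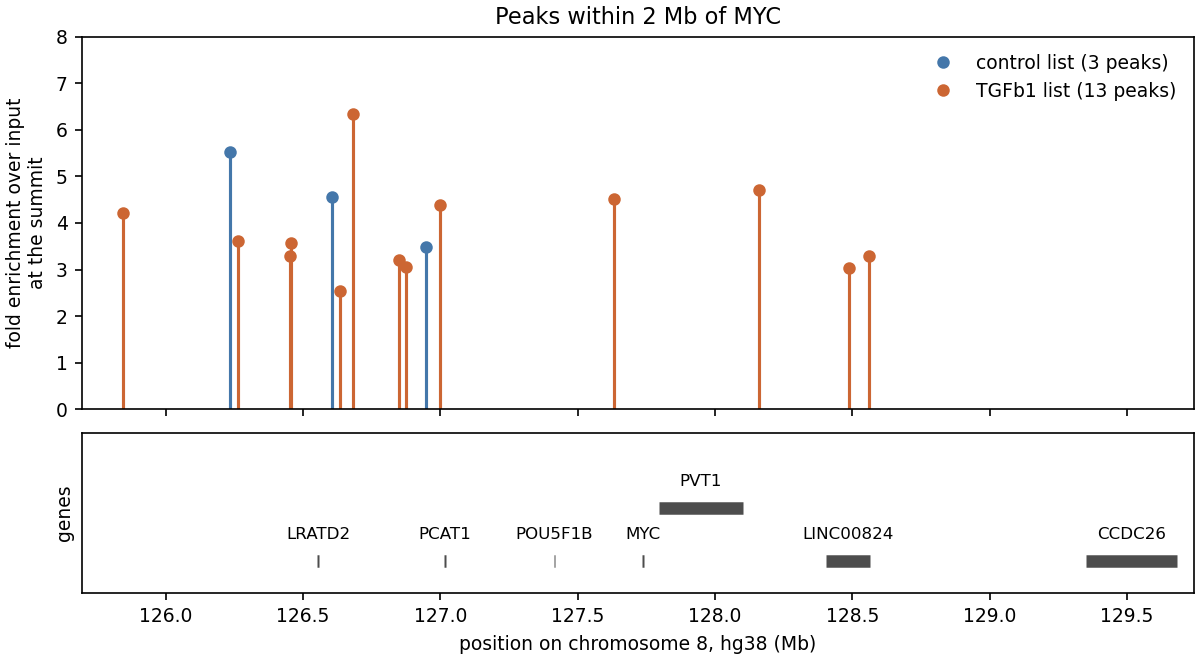
Peaks within 2 Mb of MYC on chromosome 8 (hg38, position in Mb on the x axis), with the authors' fold enrichment over input at each summit on the y axis and gene bodies beneath. The 3 control and 13 TGF-β1 peaks lie apart from one another, and none is in MYC, PVT1 or CCDC26.

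Neither list was richer in this region than in random windows of the same length, of which 73.9% held at least 3 control peaks and 71.9% at least 13 TGF-β1 peaks. The region took 0.0565% of the control list (0.0192% to 0.166%) and 0.0813% of the TGF-β1 list (0.0475% to 0.139%), a difference within the intervals. With a −log10 q of at least 5, 2 control peaks and 1 TGF-β1 peak were left.

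SMAD7, SKIL and ID1, which respond early to TGF-β in many cell types, had no peak assigned to them in either list. For SMAD7, which encodes the inhibitory SMAD of the pathway, the nearest TGF-β1 summit was 194 kb and the nearest control summit 426 kb away. The distances were 284 kb and 122 kb for SKIL, which encodes a SMAD corepressor, and 111 kb and 214 kb for ID1, an inhibitor of differentiation. The erythroid transcription factor genes were also without an assigned peak. TGF-β1 summits lay 53.7 kb from GATA1, 108 kb from KLF1, 120 kb from TAL1 and 71.4 kb from BCL11A, the repressor of fetal globin, and control summits 928 kb, 267 kb, 1718 kb and 266 kb away. At GATA1 and BCL11A the summit was within 100 kb but nearer to another gene.

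Of 39 TGF-β response genes, 10 had a TGF-β1 peak and 1 a control peak. Random matched lists had 12.5 and 4.30 on average, and the observed numbers stood at percentiles 18.0 and 3.19. The members of highest fold were NEDD9, a scaffold protein gene (5.73), TGIF1, a SMAD corepressor gene (4.46), BHLHE40 (4.17) and LTBP2 (3.80), and the control peak was near BAMBI, a pseudoreceptor gene (3.02). TGIF1 (chromosome 18, 3412009 to 3459978) had 4 TGF-β1 peaks, of which 3 lay in the gene with folds of 3.22, 2.67 and 2.76. Of 24 SMAD pathway genes, 9 had a TGF-β1 peak (random mean 9.40, percentile 42.9) and 3 a control peak (3.65, percentile 36.8). These included the receptor genes ACVR1 (5.32), ACVR2A (5.07) and TGFBR3 (4.71) and the ligand gene TGFB2 (4.52) in the TGF-β1 list, and BMPR1A (4.57) and TGFBR3 (3.28) in the control list.

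The globin genes stood apart from random lists in the TGF-β1 list, with 4 of 10 genes against a random mean of 0.177 (percentile 99.995). In the control list 0 of 10 had a peak against a mean of 0.0554 (percentile 47.3). These are the peaks of the β-globin locus described above, with the HBG1 and HBG2 peaks uncertain as to gene, so the 4 genes are 1 locus and the percentile adds nothing to the count there. Other erythroid genes had a peak in 6 of 38 cases in the TGF-β1 list (random mean 10.1, percentile 4.17) and in 0 of 38 in the control list (3.57, percentile 0.935). Among them were RHAG (4.06) and TFRC, which encodes the transferrin receptor (3.80). Heme synthesis and iron genes had 4 of 23 (4.53, percentile 39.9) in the TGF-β1 list, TFRC (3.80), SLC11A2 (3.69), CPOX (3.05) and SLC40A1 (2.34), and 1 in the control list, CPOX (3.56), against a mean of 1.39 (percentile 40.75).

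Stem and progenitor cell genes had a TGF-β1 peak in 10 of 30 (random mean 12.0, percentile 19.9) and a control peak in 4 of 30 (4.78, percentile 35.6). HOPX (4.97), MECOM (4.52), HLF (4.46) and ERG (4.22) led in the TGF-β1 list, and HOPX (5.13) and ERG (4.57) in the control list. Megakaryocyte genes had 3 of 20 (3.78, percentile 31.6), among them CD9 (5.58) and VWF (4.05), and 0 in the control list (1.30, percentile 12.1). Myeloid genes had 6 of 24 (4.31, percentile 83.3), led by ITGAM (5.16), VCAN (4.31) and LTF (3.39), and 0 in the control list (1.38, percentile 11.1). Mast cell, basophil and eosinophil genes had 1 of 10 (1.62, percentile 32.5), CPA3 (3.55), and 0 in the control list (0.503, percentile 29.7). Lymphoid genes had 3 of 22 in each list, PAX5 (4.25), EBF1 (3.29) and RAG1 (3.04) with TGF-β1 (4.49, percentile 19.4), and IL2RB (3.29) and LEF1 (2.66) among those of the control (1.66, percentile 85.6).

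Genes of other cell types were near their random means. Stromal and stellate cell genes had 5 of 16 (random mean 5.50, percentile 39.7), led by RELN (5.87), LRAT (3.80), RGS5 (3.38) and COL1A1 (3.05), and 2 in the control list (2.01, percentile 52.5), RELN (4.49) and POSTN (2.86). Endothelial genes had 4 of 11 (3.21, percentile 72.4), SOX17 (4.22), KDR (4.06), TIE1 (3.81) and PECAM1 (2.80), and 1 in the control list, CLDN5 (4.83), against 1.26 (percentile 43.4).

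MYC network and target genes had 4 of 20 in the TGF-β1 list (3.80, percentile 56.5), MYCN (5.09), MXI1 (3.25), MAX (2.88) and MYCL (2.68), and 0 in the control list (1.198, percentile 13.8). These summits lay inside MXI1, 8.9 kb from MYCL, 71.6 kb from MYCN and 89.5 kb from MAX. The MYCL peak was over high local background. Cell cycle genes had 3 of 28 (5.98, percentile 5.745), RBL2 (4.06), CCNE1 (4.06) and CDKN2A (3.65), and 2 in the control list (1.93, percentile 55.1), RBL1 (3.43) and CCND3 (3.09). Immediate early genes had 2 of 23 in each list, JUN (2.79) and KLF6 (2.79) with TGF-β1 (4.67, percentile 6.255), and DUSP5 (3.36) and KLF4 (3.36) in the control (1.46, percentile 69.6). Chromatin looping and co-factor genes had 5 of 20 (7.65, percentile 9.33), led by the cohesin gene STAG1 (3.79), KDM1A (3.47), the cohesin gene SMC3 (3.21) and HDAC2 (3.05), and 1 in the control list, STAG1 (4.10), against 2.82 (percentile 11.5). Ribosomal protein genes had 8 of 84 (7.74, percentile 55.35), led by RPS23 (4.15), RPLP1 (4.06), RPL39L (3.96) and RPS12 (3.96), and 2 in the control list (2.36, percentile 43.8), RPL29 (4.37) and RPS12 (3.28). Olfactory receptor genes had 55 of 392 (44.5, percentile 96.0), led by OR4D10 (5.53), OR1J2 (5.27), OR5AN1 (5.17) and OR2L13 (5.07), and 19 in the control list (13.3, percentile 94.15), led by OR4C15 (5.66) and OR4A16 (5.35).

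**Figure D3:**
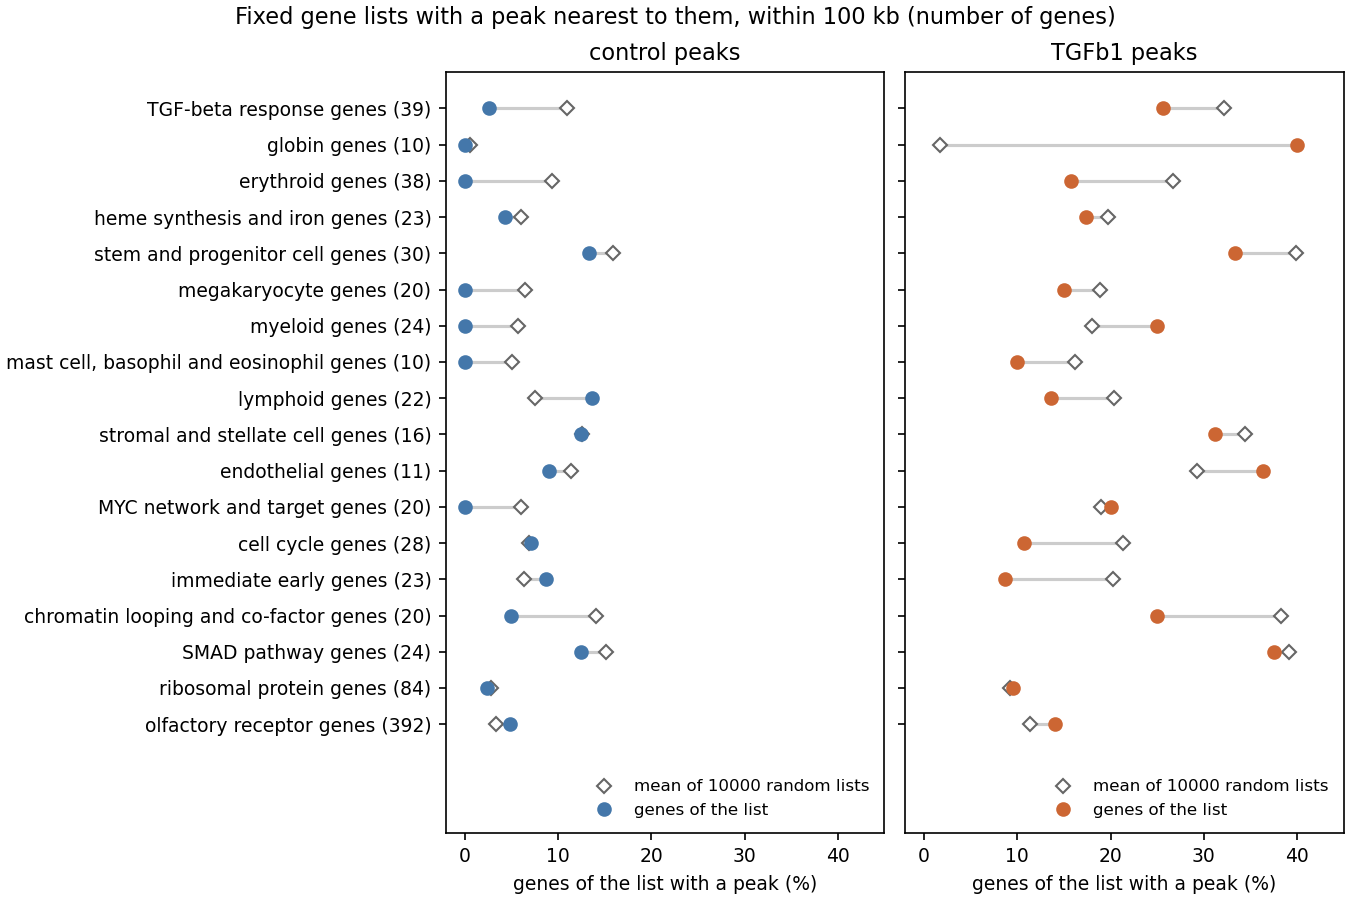
Share of each fixed gene list with a peak nearest to it within 100 kb (x axis, percent of genes; the number of genes is beside each name), for control peaks on the left and TGF-β1 peaks on the right. Filled points are the list and open diamonds the mean of 10000 matched random lists; the globin genes of the TGF-β1 list, 4 of 10, lie furthest from their diamond.

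Over all 813 genes, 41 had a control peak and 138 a TGF-β1 peak, and of the 18 lists 1 lay outside the 2.5 to 97.5 percentiles in each list of peaks, the erythroid genes in the control and the globin genes in the TGF-β1 list. In simulated lists with no effect this share was 6.5%, so the count of 1 list in 18 does not by itself speak against chance. The simulated lists had a single size and other rates of peaks than these lists. Such a count also does not weigh how far outside a list lies. The globin genes of the TGF-β1 list stood at percentile 99.995, and at 100.0 in each alternative, but they are 1 locus. The control erythroid genes stayed outside with lists of equal length (percentile 0.965) and over low local background only (1.14). In the other settings their count of 0 had a random mean of at most 1.19 and could not fall outside. With lists of equal length, 3 lists of the TGF-β1 peaks were outside, the globin genes, the olfactory receptor genes (30 against a random mean of 16.1, percentile 99.955) and the chromatin looping and co-factor genes (0 against 3.65, percentile 0.545). The random lists draw genes apart from one another, whereas the globin and olfactory receptor genes lie in clusters, so their percentiles count neighbours as separate genes. With summits within 10 kb of a gene end in place of the nearest gene, 24 and 73 genes had a peak.

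The strongest TGF-β1 peaks without overlap lay mostly far from genes. Of the 10 TGF-β1 peaks of highest fold without overlap, 7 were over 500 kb from a protein-coding gene and 6 lay in dense bins. The highest was inside PTPRD, a receptor phosphatase gene (chromosome 9, 9442093 to 9442239, fold 9.88, −log10 q 23.3). Next to genes lay the peaks inside C5, the complement gene (chromosome 9, 120993446 to 120993593, fold 7.35), and 5.15 kb from MSGN1 (chromosome 2, 17811224 to 17811393, fold 7.64). The others were nearest to ANKRD30B (3 peaks, folds of 9.51, 8.39 and 7.79), NCAM2 (8.19), ROCK1 (7.54), ZNF337 (7.44) and ZNF33B (7.30), at distances of 0.521 to 2.08 Mb. The 5 control peaks of highest fold without overlap were 29.6 kb from TRAF3IP2 (fold 8.05), inside CSMD3 (6.72), 534 kb from SPATA31A1 (6.71), inside ARHGEF17 (6.64) and 10.8 kb from KERA (6.60), and none lay in a dense bin. Lack of overlap is a property of the peak and not of its gene. Within 100 kb, the control list also had 4 peaks assigned to PTPRD, 2 to ROCK1 and 1 to C5. Within that distance it had none for ANKRD30B, NCAM2, MSGN1, ZNF337 and ZNF33B. The limit leaves out distant peaks, as most of the TGF-β1 peaks named here were. Control peaks did lie in the dense bins of the ANKRD30B peaks (4 and 3), the ZNF337 peak (7) and the ZNF33B peak (102). Within 100 kb, the TGF-β1 list had 4 peaks assigned to CSMD3 and none to ARHGEF17 or KERA. The 10 shared TGF-β1 peaks of highest fold included summits inside CFAP44 (7.06) and ABI3BP (6.03). The rest were nearest to LOC124901649 (8.25), LOC107985915 (7.21), SLITRK1 (5.87), ZNF716 (2 peaks, 5.41 and 5.25), UBE3D (5.32), OR11H1 (5.25) and HS3ST4 (5.23).

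The TGF-β1 list was 3.01 times as long as the control list (15993 and 5307 peaks, ratio interval 2.92 to 3.11) and covered 2754 kb against 1183 kb. Median fold was 3.46 in the TGF-β1 list and 2.97 in the control list, and median peak length 159 bp and 177 bp. Split by local background, the median folds were closer over low background, at 3.65 (TGF-β1) and 3.54 (control). Over high background they were 2.57 and 2.00. Peaks with a fold of at least 5 numbered 977 and 242. Over low local background the TGF-β1 list had 13203 peaks and the control list 3155, a ratio of 4.18. Over high local background it had 2790 and the control 2152, which was 17.4% (16.9% to 18.0%) of the TGF-β1 list and 40.6% (39.2% to 41.9%) of the control list. With a −log10 q of at least 10 the lists were of equal length within counting error, 1401 and 1388 (ratio 1.01, 0.936 to 1.09), made up of 250 and 21 peaks over low background and 1151 and 1367 over high background.

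Most shared peaks lay over high local background. Of the control peaks, 765 overlapped a TGF-β1 peak, or 14.4% (13.5% to 15.4%), against 0.457% after random placement and 2.39% after shifts. Of the TGF-β1 peaks, 770 overlapped a control peak, or 4.81% (4.49% to 5.16%), against 0.155% and 0.792%. These shares depended on the limits, at 1.07% of either list with lists of equal length by fold and 21.7% and 10.9% with a −log10 q of at least 5. Of the 765 shared control peaks, 664 (86.8%) were over high background. Outside the dense bins the shares were 3.003% (2.46% to 3.66%) of control and 0.838% (0.686% to 1.02%) of TGF-β1 peaks, against highest values of 0.506% and 0.150% over the random placements.

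Peaks of both lists were sparse at the ends of genes. Within 1 kb of either end of a protein-coding gene lay 0.639% of control peaks (31 of 4853, 0.450% to 0.905%) and 0.774% of TGF-β1 peaks (122 of 15753, 0.649% to 0.924%), against 2.34% in both cases after random placement. Outside the dense bins the shares were 0.948% and 1.08%. Inside protein-coding genes lay 26.4% and 31.4% of the peaks, against 41.8% at random in both cases, and outside the dense bins 40.5% and 43.6%. More than 500 kb from any gene lay 19.5% of control and 22.8% of TGF-β1 peaks, against 5.34% and 5.09% at random, and outside the dense bins 0.853% and 0.618%. The random placements were of all peaks over whole chromosomes, dense bins included. No random share was computed for the peaks outside the dense bins. The difference between the lists at gene ends was within the intervals.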

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

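The alternatives without dense bins, at low local background only, scaled to the control tag number and with other limits for high background were chosen after the data were seen. No paired analysis was possible because each group held 1 library. The counts of 0 at the α-globin locus and of 0 (control) and 4 or 5 (TGF-β1) at the β-globin locus held under every alternative run for them. With a −log10 q of at least 5 the lists held 2487 control and 4978 TGF-β1 peaks, 21.7% and 10.9% of them shared, 0.429% and 0.552% at gene ends, 11 and 29 fixed-list genes had a peak, and 1 TGF-β1 peak was left in the MYC region. With a −log10 q of at least 10 the lists held 1388 and 1401 peaks, and with a fold of at least 5 they held 242 and 977. Without dense bins the control list held 3164 peaks, shared shares were 3.003% and 0.838%, and shares at gene ends 0.948% and 1.08%. At low local background the control list held 3155 peaks and the shared shares were 3.14% and 0.750%. Overlap of at least 50% of both peaks gave 13.4% and 4.45%, gaps of up to 500 bp gave 15.7% and 5.60%, and removal of the top 1% of pileup gave 11.9% and 3.96%. With lists of equal length by fold, 1.07% of either list was shared, 63 fixed-list genes had a TGF-β1 peak and 5 TGF-β1 peaks were left in the MYC region. Within 5 kb of a gene end lay 4.86% and 5.55% of peaks, and within 1 kb of any annotated gene's end 2.97% and 2.91%. Summits within 10 kb of a gene end gave 24 and 73 fixed-list genes and within 1 kb 2 and 8. High background set at 3 times the genome-wide value took in 57.0% and 26.0% of peaks, and at 10 times 37.7% and 10.4%. Of 180 values for single gene lists under alternatives 91 moved and 89 did not, and of 440 for named genes 133 moved. The causes of these shifts were not tested. The length of the control list limits its counts at single loci, since 0 of 5307 peaks at β-globin allows a share of up to 0.0565%, above the 0.0313% of the whole TGF-β1 list but below the 0.0754% of a TGF-β1 list of equal length. The interval of that 0.0754% (0.0293% to 0.194%) overlaps the interval of 0 of 5307 (0% to 0.0723%). Scaling to the control tag number was run on the TGF-β1 list alone, and the motif alternatives were not run.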

Other observations

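The tests in this part were chosen after the results had been seen, except the limit of 10 on −log10 q applied to the whole lists, which was planned. Peaks of both lists crowded into 65 bins of 1 Mb, most of them near centromeres, which held 1689 control and 4420 TGF-β1 peaks. The fullest were on chromosome 1 from 123 to 124 Mb (198 control and 401 TGF-β1 peaks) and from 124 to 125 Mb (215 and 378), and on chromosome 13 from 17 to 18 Mb (136 and 410). In 14 of the bins the control list had more peaks, 590 against 202, although its whole list was the shorter one. These included chromosome 4 from 49 to 50 Mb (118 and 17), chromosome 1 from 143 to 144 Mb (83 and 1) and chromosome 20 from 31 to 32 Mb (44 and 1). The control peaks there lay over a median local background of 125 tags.

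Of 16 genes of abundant non-coding RNA looked up, 3 carried a TGF-β1 peak and 13 did not. RN7SK, which encodes the RNA that holds the elongation factor P-TEFb inactive (chromosome 6, 52995620 to 52995951), had a peak with a fold of 4.74 and a −log10 q of 16.4. RN7SL1 (chromosome 14, 49586580 to 49586878) and RN7SL2 (chromosome 14, 49862551 to 49862849), the RNA genes of the signal recognition particle, had peaks with folds of 3.67 and 5.79 and −log10 q of 9.67 and 20.8. RN7SL1 and RN7SL2 are nearly identical in sequence, so reads can be placed in either and these peaks are uncertain as to gene. Among 12082 genes of up to 6 kb, RN7SL2, RN7SK, HBB and RN7SL1 held the highest −log10 q of the 63 TGF-β1 summits. In the control list 10 summits fell in such genes, none in these 4 genes, and the highest −log10 q was 5.70.

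The TGF-β1 list was longer than the control list. Over low local background a deeper ChIP library does not account for the gap, since the ratio there was 4.03 (3.49 to 4.66) for peaks with a fold of at least 5, at a tag ratio of 1.27, and thinning the TGF-β1 peaks to the control tag number left 11063 of 13203, or 3.51 per control peak (3.37 to 3.65). Over high local background the ratio of 1.30 (1.23 to 1.37) holds the tag ratio, and whether depth accounts for it was not decided. The ratio was 1.24 (1.17 to 1.31) after thinning and 0.842 (0.778 to 0.911) at a −log10 q of at least 10. Depth alone would not leave fewer peaks at that limit, where the whole lists had a ratio of 1.01 (0.936 to 1.09). Both bounds were set after these values had been seen, however, and the intervals treat peaks that crowd into the same bins as independent. Repeat clusters at centromeres do not account for the gap, as the ratio outside the dense bins was 3.58. The TGF-β1 input held 0.703 times as many tags and its ChIP tags were 43 bp against 60 bp, which cannot be told apart from treatment with 1 library per group, and a change of binding with TGF-β1, the biological explanation the design names, was not tested.

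The peaks shared by both lists may come largely from repeats, since 30.9% of control peaks over high local background overlapped a TGF-β1 peak and 3.20% of those over low background did. Local crowding of peaks alone gives too little overlap, as the share over low background was 5.32 times the highest of 1000 shifts by 10 to 50 kb. Sites bound in both conditions remain a biological explanation for these 101 control peaks, untested without replicates.

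The β-globin peaks of the TGF-β1 list are the pattern closest to the title of the series. Reads shared between HBG1 and HBG2 do not account for all of them, since 3 of the 5 lie outside these genes. Reads shared among other globin genes, such as HBB and HBD, were not tested. Of the 4 peaks in HBB, HBG1 and HBG2, a median of 4 (95% of draws 4 to 4, lowest 3) were called in 10000 draws thinned to the control tag number. Fewer tags alone therefore do not remove these 4 peaks from this library. The draws resample peaks already called, so they do not show how often a separate library of that depth would call them. The peak beside HBE1 was called in 27.1% of draws and may owe its call to depth. Reads from abundant RNA stay open. The 2 of 15 further non-coding genes with a peak, RN7SL1 and RN7SL2, are near-identical copies. They were looked up after RN7SK had been seen and decide nothing. Neither HBA1 nor HBA2 had a peak. Of 42 abundant messenger RNA genes 1 had a peak, HSP90AA1, and it was weak (fold 2.88, −log10 q 2.01). RNA levels were not measured here. Peaks confined to exons would point to RNA or cDNA, but exon positions were not analysed here, so RNA and the differences in input and tag length cannot be told apart from binding at these genes under TGF-β1, which was not tested.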
